A study of Rattus norvegicus with 18 samples.

How the data were processed

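Kidney RNA of male rats aged 30 days was measured on 18 Affymetrix rat expression arrays, 3 for each of 6 strains (SD, PCK, FHH, FHH.Pkhd1, SS and SS.Pkhd1). Per the labels, RNA of 4 animals was pooled for each strain and amplified with a two-cycle cDNA kit before hybridisation, so the 3 arrays of a strain are technical repeats of 1 pool. The deposited values are on a log2 scale, and the submitters' processing notes name GCOS and RMA, with no version and no parameters given in the sources used here. RMA, per its usual definition, corrects background, applies quantile normalization over probes and summarises each probe set. The values were checked to be log2: they were neither linear nor centred per gene. No further transformation was applied for the reported values, and the number of arrays limits their precision.

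The deposited table held 31099 probe sets. The 57 array control probe sets were set aside as measures of array quality, which left 31042 probe sets for testing. The annotation gave 1 gene symbol for 20826 of these, several symbols for 436 and none for 9780. A gene was represented by its probe set with the highest mean over the 18 arrays among those with 1 symbol, which gave 14217 genes. The symbols were brought up to date through the gene identifiers of the rat reference annotation (GRCr8), which held no entry for 68 of the single symbols. The reference served for names and for gene order only. Pkhd1 itself was not analysed here, as no probe set in the annotation used carried its symbol.

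The comparisons, gene lists, thresholds and rule for naming genes were fixed before the data were examined. One linear model with a coefficient for each strain was fitted to the 18 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom and a prior of 5.73 degrees of freedom. It gave 9 contrasts: 3 of a cystic strain against its parental strain, 3 differences between these effects, and 3 between parental strains. A probe set was called when its Benjamini-Hochberg adjusted p over the 31042 probe sets was under 0.05 and its difference was at least 1.5-fold. Adjusted p-values of single genes come from this limma fit. Standard errors are those of the limma coefficients and standard deviations are over the 3 arrays of a strain. The standard error of the proximal tubule median is the exception and comes from the spread of its 28 genes. Probe sets called in the same direction in the 3 cystic strains were counted. Their expected number is the product of the 3 shares called, taken as independent. An effect across backgrounds was tested with limma on the 6 pool means with the background as a covariate, with 2 residual degrees of freedom and the adjusted p as the only threshold.

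The 32 gene lists held 612 symbols, of which 542 were measured. They covered tubule injury, principal, intercalated, proximal tubule, loop of Henle and distal convoluted tubule, podocyte, endothelial, extracellular matrix and fibroblast, smooth muscle, macrophage and myeloid, antigen presentation and lymphocyte genes. They also covered inflammatory signals, the interferon response, complement and acute phase, cell division, cyclic AMP and chloride secretion, cystic disease and cilium, EGF receptor, Wnt and renin-angiotensin genes. The metabolic and response lists were cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, glutathione and oxidative stress, xenobiotic and steroid metabolism, osmotic response and immediate early genes. Lists of urothelium, red blood cell, adipose tissue and adrenal gland genes stood for other tissue in the sample. For each list the called members were counted, also with p adjusted over the list alone. The median of each list was ranked among 10000 random lists matched on 20 expression bins, a rank that ignores correlation between genes. Each list was also tested across backgrounds with camera, with its preset correlation of 0.01 and with an estimated correlation.

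The named genes were, per cystic strain, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between strains. To these were added up to 4 called members of each list per comparison, and up to 4 uncalled members where a list is described. For genes called alike in the 3 backgrounds, the 10 rises and 10 falls with the largest smallest effect were named. For each difference of effects and each parental contrast the 3 highest and 3 lowest called genes were named, and across backgrounds the 5 rises and 5 falls with the smallest p. Genes outside this rule are marked as chosen after their values were seen.

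The alternatives tried were quantile normalization or median centring on top of the deposited values, a filter on dim probe sets, a fold floor of 2 or none, limma treat at 1.2-fold, array weights and a trended robust prior. Others were 1 probe set per gene, the mean of the probe sets of a gene, only the arrays of the strains compared, the array number as a block, and each array left out in turn. The fit across backgrounds was also run without the background term, without each background, and on all arrays with the pool as a random block. Cyclic loess normalization and fits without the arrays whose controls stood apart were added after seeing the data. Other splits of the arrays were fitted with the same model.

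The calls were tested on simulated data with the array spread of these data, averaged over the 6 strains. No trend with brightness was simulated, and few probe sets were changed (67 of 31042 at 1.5-fold). The SS.Pkhd1 arrays scattered more than that average, so the shares and false calls below need not hold for contrasts with SS.Pkhd1. At a true difference of 1.5-fold, 35.8% of changed probe sets were recovered for PCK, 31.3% for FHH.Pkhd1 and 25.4% for SS.Pkhd1. This difference equals the fold floor, so estimates scatter to both sides of it and many miss the call however precise they are. Shares at 1.5-fold, also for calls alike in 3 backgrounds, therefore reflect the floor as well as the array error. The lowest and highest shares over the 9 contrasts were 16.4% and 47.8% at 1.5-fold, 58.2% and 97.0% at 2-fold, and 97.0% and 100% at 4-fold, with at most 6 false calls. For calls alike in 3 backgrounds the shares were 2.99%, 91.0% and 100% at these folds. The fit across backgrounds recovered 0% at each fold with a spread taken from the pool means of SD, PCK, FHH and FHH.Pkhd1. That spread holds the difference between the PCK and FHH.Pkhd1 effects, as no strain had a repeat pool. With array error alone the fit recovered 80.6%, 95.5% and 100%. Camera recovered the 1 list that was changed, with 0 false calls. Genes were simulated without correlation, so this does not cover lists whose members move together. In the real data the estimated correlation was 0.87 for the lymphocyte and 0.79 for the oxidative phosphorylation list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.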

Results

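Gene expression was measured in kidneys of rats, male per the labels and aged 30 days, from 3 strains with a polycystic kidney and their 3 parental strains, on 18 arrays. The PCK rat, a model of autosomal recessive polycystic kidney disease with a mutation in Pkhd1, was compared with the Sprague Dawley strain (SD). FHH.Pkhd1 and SS.Pkhd1, which carry the PCK mutation on the Fawn-Hooded Hypertensive (FHH) and Dahl salt-sensitive (SS) backgrounds, were compared with FHH and SS. SS.Pkhd1 is recorded with 5 backcross generations, and no number is recorded for FHH.Pkhd1. Per the series text, the age was that of the greatest difference in cyst formation between the cystic strains, and each was set against its parent so that strain differences unrelated to severity would drop out. Each strain was represented by 1 pool of RNA from 4 animals, hybridised to 3 arrays. The p-values and errors below cover array error only, as n = 3 counts repeat arrays of 1 pool. The median log2 signal of the strains lay between 4.66 in SS and 4.91 in SS.Pkhd1.

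The arrays of SS.Pkhd1, and to a smaller degree those of PCK, stood apart from the rest in their control probe sets. The poly-A spike-in controls, RNAs added before labelling, had a log2 signal of 11.96 ± 0.02 in SS.Pkhd1 and 9.44 ± 0.16 in SS (SD, n = 3 arrays). In PCK they stood at 10.67 ± 0.02 and in SD at 9.27 ± 0.06, whereas FHH.Pkhd1 (9.61 ± 0.04) and FHH (9.96 ± 0.02) lay closer together. The 5S ribosomal RNA probe sets were 4.05 log2 higher in SS.Pkhd1 than in SS, 1.28 higher in PCK than in SD, and fell by 0.45 in FHH.Pkhd1. Beta-actin signal from the middle of the transcript fell by 4.92 in SS.Pkhd1 and by 2.12 in PCK, and was 0.29 higher in FHH.Pkhd1. Correlations between arrays of the 4 other strains ran from 0.986 to 0.992. Those of PCK with these 4 strains ran from 0.946 to 0.965, and those of SS.Pkhd1 from 0.723 to 0.780. The standard deviation of signal over all probe sets was 1.57 in SS.Pkhd1 and 2.15 in SS. Arrays within SS.Pkhd1 correlated at 0.957 to 0.964, against 0.994 to 0.997 within the other strains. The model shared 1 spread between all strains, so errors and p-values of comparisons with SS.Pkhd1 do not show the wider scatter of its arrays.

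**Figure D1:**
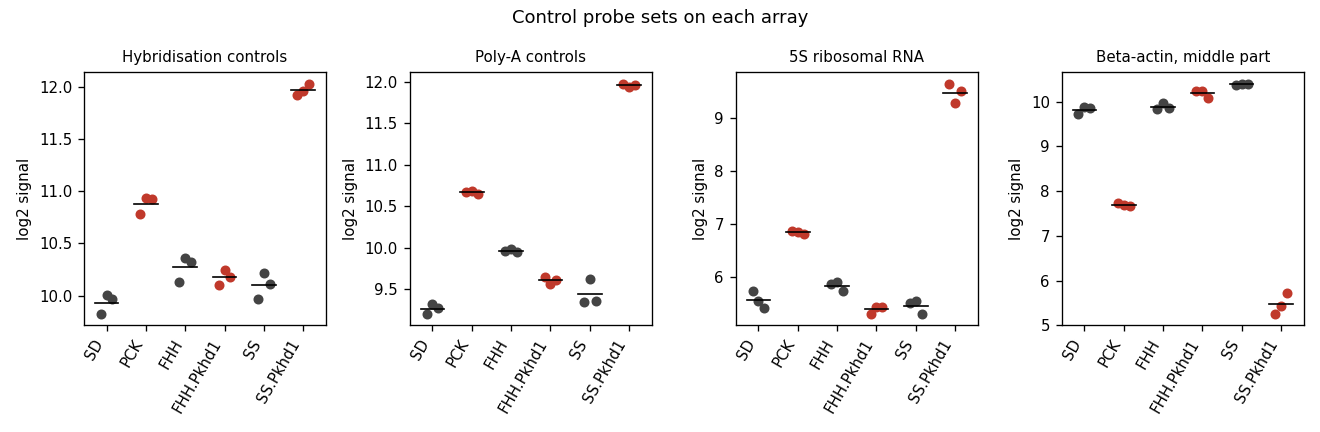
Mean log2 signal of 4 kinds of control probe sets on each of the 18 arrays, by strain; points are arrays, bars are strain means, and cystic strains are in red. The SS.Pkhd1 arrays had the highest hybridisation control (11.97), poly-A control (11.96) and 5S ribosomal RNA (9.48) means and the lowest beta-actin mean (5.47).

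FHH.Pkhd1 was compared with FHH to ask which genes differ between a cystic strain and its parent on the FHH background, where the poly-A controls fell by 0.36 on the FHH.Pkhd1 arrays. Cyp4a8, a cytochrome P450 that hydroxylates fatty acids, fell by 4.15 ± 0.09 on the log2 scale (SE, n = 3 arrays per strain; adjusted p = 9.25e-16). The organic anion transporter Slco1a1 fell by 4.44 ± 0.17 (adjusted p = 2.95e-12), the short-chain dehydrogenase-like Dhrs7l1 by 5.41 ± 0.13 and the aldo-keto reductases Akr1c13 and AKR1C3l1 by 4.07 ± 0.11 and 3.78 ± 0.12. Tff3, a trefoil peptide of epithelia, fell by 3.58 ± 0.08, and the amino acid transporter Slc7a12 by 3.69 ± 0.12. Dmrtc1c1, Ugt2b35 and Nat8f3 completed the 10 largest falls, at -2.68, -2.67 and -2.37.

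Albumin (Alb) had the largest rise, from 3.45 to 6.42 (log2 difference 2.98 ± 0.11, adjusted p = 2.03e-12). The circadian genes Dbp, Per2 and Per3 rose by 2.24 ± 0.10, 1.97 ± 0.11 and 1.5 ± 0.15. Cyp1a1, a target of the aryl hydrocarbon receptor, rose by 2.07 ± 0.12 and the monocyte chemokine Ccl2 by 1.95 ± 0.10. Havcr1, which encodes kidney injury molecule KIM-1, rose by 1.5 ± 0.16 (adjusted p = 1.11e-05), and the fatty acid receptor Cd36 by 1.45 ± 0.13. Oacyl and the alcohol dehydrogenase Adh1c completed the 10 largest rises, at 1.66 and 1.27.

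**Figure D2:**
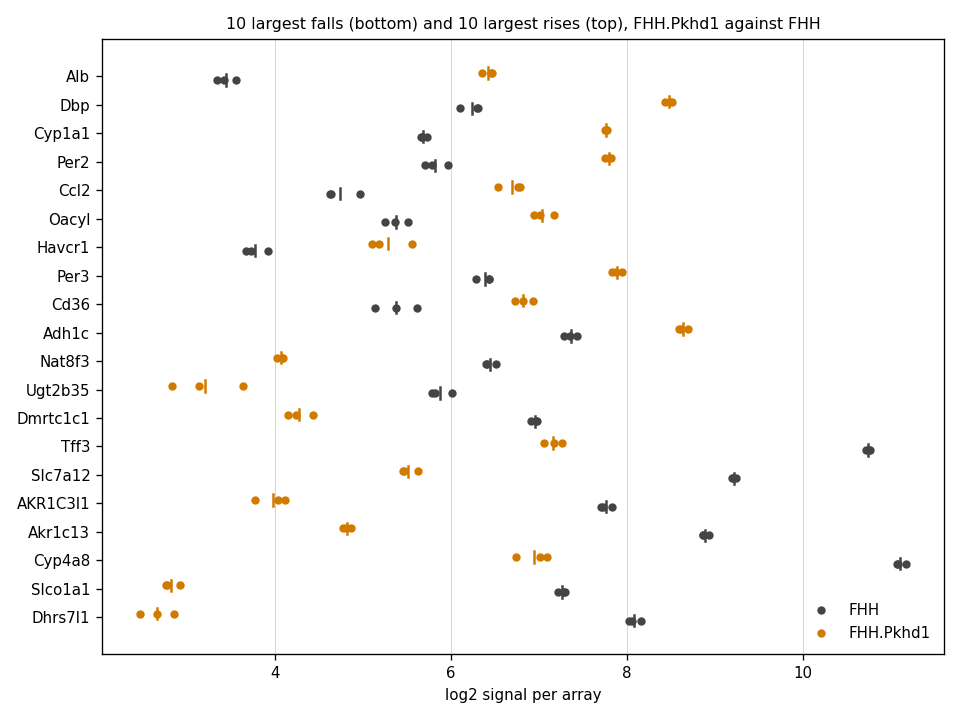
log2 signal on each FHH (grey) and FHH.Pkhd1 (orange) array for the 10 largest rises and 10 largest falls; points are arrays and vertical bars are means of 3 arrays. Dhrs7l1 had the largest fall, from 8.08 to 2.67, and Alb the largest rise, from 3.45 to 6.42.

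Among the gene lists, tubule injury had 4 members higher and 1 lower of 23 measured. Beside Havcr1 these were osteopontin (Spp1, 0.69 ± 0.10, adjusted p = 0.000349), clusterin (Clu, 0.69 ± 0.10) and lipocalin 2 (Lcn2, 0.69 ± 0.15), whereas the cell cycle inhibitor Cdkn1a fell by 0.72 ± 0.11. The extracellular matrix and fibroblast list had 3 higher of 31 (Dcn 0.92 ± 0.09, Lox 0.66 ± 0.13 and Col3a1 0.62 ± 0.10) and 0 lower. Smooth muscle had 2 of 11 higher (Myh11 0.76, Actg2 0.71), inflammatory signal 2 of 20 (Ccl2 and Ptgs2, at 1.95 and 1.04) and complement and acute phase 2 of 13 (the fibrinogen gene Fgb at 0.92, and again Lcn2). Osmotic response had 2 of 8 higher (Hspa1a 0.70, Akr1b1 0.63), adipose tissue 2 of 10 (Ucp1 1.0, Cidea 0.65) and immediate early 2 of 15 (Fos 1.08, Ier3 0.69). Cholesterol synthesis had 2 of 18 lower, Dhcr7 (-1.02 ± 0.15) and Idi1 (-0.60 ± 0.10), with a list median of -0.21 at percentile 0.01 of matched random lists. At the other extreme, at percentile 99.9 or above, lay the medians of the lists of tubule injury (0.28), principal cells (0.22), endothelium (0.20), extracellular matrix and fibroblast (0.18), fatty acid oxidation (0.17), osmotic response (0.27) and adipose tissue (0.29). Tubule injury and matrix were as extreme between parental strains, at percentile 100 in SS against SD and at 0.01 and 0 in FHH against SS. Principal cells, endothelium, fatty acid oxidation and osmotic response did not reach 99.9 between parental strains. With 1 pool per strain, such a rank does not set a cystic effect apart from a difference between pools. Xenobiotic and steroid metabolism had 3 of 20 lower (Slco1a1, Cyp4a8 and Cyp2j4, the last at -1.05) and 1 higher (Ugt8, 1.18), and its median of 0.06 and mean of -0.36 differed in sign. The renin-angiotensin and vasoactive list had 2 of 16 lower, angiotensinogen (Agt, -1.47 ± 0.10) and Cyp4a8, with a median of 0.01 and a mean of -0.26.

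The proximal tubule list had 1 of 28 higher (Slc22a8, 0.64) and 1 lower (the organic cation transporter Slc22a2, -2.07 ± 0.10), with a median of 0.0044 and a mean of -0.05. Single calls were made in the lists of principal cells (Scnn1a, 0.66, of 12), cell division (Bub1b, 0.72, of 28), fatty acid oxidation (Pdk4, 0.62, of 21) and glutathione and oxidative stress (Sod3, 0.66, of 23). Cftr, the chloride channel of the cyclic AMP list, fell by 0.65 and was its 1 call of 21. Hsd3b1 of the adrenal list fell by 0.71, its 1 call of 9. The lists of intercalated cells, loop of Henle and distal convoluted tubule, podocytes, endothelium, macrophages, antigen presentation and lymphocytes each had 0 calls with limma. So did those of the interferon response, cystic disease and cilium, EGF receptor, Wnt, oxidative phosphorylation, urothelium and red blood cells. The counts were the same when adjusted over the list alone, except that immediate early genes then had 3 higher.

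In all, 576 of 31042 probe sets were called (355 higher, 221 lower), which represent 293 genes, by the limma test over the 18 arrays. The excess of higher calls depended on the settings, with 204 higher and 185 lower of 389 after quantile normalization, and 40 higher and 72 lower with a 2-fold floor. After quantile normalization of the deposited values the calls of Ptgs2, Fos, Lox, Col3a1, Lcn2, Hspa1a, Akr1b1, Ucp1, Scnn1a, Pdk4, Sod3 and Hsd3b1 ended, with unchanged direction. Without a single array, those of Hsd3b1 (between -0.67 and -0.76 without any 1 of the 6), Ptgs2, Lcn2, Idi1, Bub1b and Cftr ended: Ptgs2 was then 0.95 without FHH array 2 and 0.98 without FHH.Pkhd1 array 1, Cftr -0.53 without FHH array 2, Lcn2 0.60 without FHH array 1 and 0.66 without FHH.Pkhd1 array 1, Bub1b 0.69 without FHH array 2 and 0.68 without FHH.Pkhd1 array 2, and Idi1 -0.56 without FHH array 1 or FHH.Pkhd1 array 2.

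PCK was compared with SD to ask which genes differ in the original model. The largest rises were the class II antigen gene RT1-Bb (4.53 ± 0.13, SE, n = 3 arrays per strain; adjusted p = 2.99e-14) and Alb (4.15 ± 0.11), followed by Fam111a (3.79 ± 0.13) and the serine protease inhibitor Serpina3n (2.78 ± 0.20). RT1-Bb was also measured by a second probe set, which was called lower. Angiotensin-converting enzyme (Ace) rose by 2.40 ± 0.13. Snap91, Stk32c, Sox11, Nexmif and Fetub, between 2.18 and 2.52, completed the 10 largest rises. The largest falls were Resp18 (-3.77 ± 0.16), soluble epoxide hydrolase (Ephx2, -3.72 ± 0.21), Ugt2b35 (-3.54 ± 0.18) and RT1-T24-3 (-3.49 ± 0.12). Carbonic anhydrase 3 (Car3), the fatty acid desaturase Scd, the water channel Aqp4, Colec12, Lrrc19 and Igfbp7 followed, between -3.39 and -2.92. These genes were measured where the poly-A controls were 1.40 and the 5S ribosomal RNA 1.28 log2 higher on the PCK arrays.

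Of the oxidative phosphorylation list 16 of 24 members fell in PCK and 0 rose (median -0.72, percentile 0.390), among them Uqcrfs1 of complex III (-2.21 ± 0.12) and Ndufs1 of complex I (-1.91 ± 0.13). Fatty acid oxidation had 10 of 21 lower and 0 higher (Etfdh -2.19 ± 0.15, Hadh -1.90 ± 0.25). The proximal tubule list had 14 of 28 lower and 1 higher, with Slc27a2 at -2.40 ± 0.08, Fbp1 at -2.27 ± 0.12 and the water channel Aqp1 at -1.92 ± 0.15. After quantile or cyclic loess normalization 8 of its members were called in place of 15, and after quantile normalization 10 each were called in the oxidative phosphorylation and glutathione lists. Glutathione and oxidative stress had 13 of 23 lower and 3 higher (Gclc -1.46 ± 0.08, Gpx3 -1.06 ± 0.08), and xenobiotic and steroid metabolism 11 of 20 lower and 0 higher (Slco1a1 -2.71 ± 0.17, Hao2 -2.39 ± 0.08). In the loop of Henle and distal tubule list the potassium channel Kcnj1 (-2.51 ± 0.11) and the sodium transporter Slc12a1 (-2.01 ± 0.10) were among 5 of 15 lower, and the thiazide-sensitive transporter Slc12a3 (1.24 ± 0.08) among 3 higher. Beta-actin from the middle of the transcript fell by 2.12 on the same PCK arrays.

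In PCK the cystic disease and cilium list had 8 of 24 members lower, 2 higher and 14 not called (median -0.41, percentile 0.370). Bbs5 and Tmem67 were lower (-1.57 ± 0.15 and -1.30 ± 0.19), as was Pkd2 (-1.57 ± 0.14), the gene of polycystin-2, whose second probe set was called higher. Extracellular matrix and fibroblast had 11 of 31 lower, 3 higher and 17 not called (Dcn -2.78 ± 0.09, Col3a1 -2.07 ± 0.10), with a median of 0.0047 and a mean of -0.33. The interferon response had 7 of 19 lower, 1 higher and 11 not called (Mx1 -2.49 ± 0.17, Ifit2 -1.43 ± 0.11). Tubule injury had 7 of 23 lower (Spp1 -2.10 ± 0.10) and 4 higher (Gdf15 1.77 ± 0.10). The red blood cell list had 4 of 7 higher and 0 lower (Alas2 1.36 ± 0.20, Hba-a3 0.93 ± 0.12). On these arrays the signal from the 3' end of beta-actin exceeded that from its 5' end by 4.30 in PCK and 3.34 in SD. For Gapdh it did so by 2.37 in PCK and 1.38 in SD.

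Both directions were found in most other lists in PCK. Cell division had 7 of 28 higher and 3 lower (Foxm1 1.01, Kif11 -1.11), macrophage and myeloid 5 of 21 higher and 1 lower (C1qc 0.92, Ptprc -1.76), and cholesterol synthesis 4 of 18 higher and 6 lower (Mvd 1.16, Msmo1 -1.58). Renin-angiotensin and vasoactive had 4 of 16 higher and 5 lower (Ace 2.40, the mineralocorticoid receptor Nr3c2 -1.77), immediate early 3 of 15 higher and 4 lower (Zfp36 0.83, Fos -1.31), and cyclic AMP and chloride secretion 3 of 21 higher and 4 lower (Slc12a2 0.78, Gnas -2.08). Wnt had 3 of 18 higher and 3 lower (Axin2 1.10, Fzd1 -1.37), complement and acute phase 3 of 13 each way (Hp 1.08, Cp -1.14), inflammatory signal 2 of 20 higher and 3 lower (Ccl20 0.66, Ccl2 -1.83), and antigen presentation 2 of 14 higher and 3 lower (RT1-Bb 4.53, B2m -1.56). Principal cells had 3 of 12 higher and 2 lower (Scnn1b 0.75, Aqp4 -3.0), podocytes 2 of 11 higher and 1 lower (Cdkn1c 0.69, Plce1 -0.74), urothelium 2 of 9 each way (Upk1a 0.86, Sprr1a -1.23) and EGF receptor 1 of 11 higher and 2 lower (Tgfa 1.32, Areg -2.20). Intercalated cells (Rhcg 1.23, Slc4a1 -0.99), endothelium (Egfl7 0.66, Sox18 -0.59) and smooth muscle (Tagln 0.83, Mylk -0.76) had 1 member each way, of 11, 14 and 11. Lymphocytes had 2 of 17 higher (Nkg7 0.74, Prf1 0.69), adipose tissue 3 of 10 lower (Fabp4 -1.20), the osmotic response 3 of 8 lower (Slc14a2 -1.03, with another of its 5 probe sets called higher) and the adrenal gland 1 of 9 higher (Dbh 0.61). Medians and means differed in sign for the endothelial, antigen presentation, inflammatory, cyclic AMP, EGF receptor, renin-angiotensin, osmotic and immediate early lists. The counts of every list in PCK were the same adjusted over the list alone. Hybridisation controls were 0.95 log2 higher on the PCK arrays than on those of SD.

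In PCK, 8216 of 31042 probe sets were called by limma (3440 higher, 4776 lower), for 4474 genes, and the median difference of all probe sets was 0.12. The balance of directions depended on the floor, with 8635 higher and 7177 lower without one, and 915 higher and 2371 lower at 2-fold. The calls of Ccl20 and Dbh ended after quantile or cyclic loess normalization (0.54 and 0.54, 0.53 and 0.53), as did that of Sox18 (-0.46 and -0.56), and those of Nkg7 and Prf1 ended after cyclic loess (0.58 and 0.57). Those of Nfat5 and Hspa1a ended after either, and those of Psmb9, Egfr, Upk2 and Upk1b after quantile normalization, all with unchanged direction. Without single arrays, Dbh was 0.47 without PCK array 1, 0.56 without PCK array 3 and 0.56 without SD array 1 or 3, Sox18 was -0.45 without PCK array 1 and -0.55 without SD array 2, and Ccl20 was 0.55 without SD array 1, each then uncalled.

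SS.Pkhd1 was compared with SS to ask which genes differ on the third background. The largest falls were Aldh6a1, a mitochondrial enzyme of valine breakdown (-7.67 ± 0.09, SE, n = 3 arrays per strain; adjusted p = 4.42e-20), Igfbp7 (-6.59 ± 0.10), the histamine methyltransferase Hnmt (-6.44 ± 0.08) and the mitochondrial transhydrogenase Nnt (-6.44 ± 0.19). Slco1a6, Atp5f1c, Gk, Slco1a3, Aadat and Col3a1 followed, between -6.42 and -5.93. The largest rises were Spetex2l1 (6.0 ± 0.14), Rd3 (3.74 ± 0.14), Zfp536 (3.70 ± 0.19), Ankrd34b (3.64 ± 0.21) and metallothionein 1 (Mt1, 3.58 ± 0.13). Sall4, Onecut1, Cpeb1, Ccr6 and Tbc1d12 followed, between 2.98 and 3.12. These values were measured where the poly-A controls were 2.52 and the 5S ribosomal RNA 4.05 log2 higher on the SS.Pkhd1 arrays. Their errors and p-values rest on the spread shared by all strains, although the SS.Pkhd1 arrays scattered more than the others.

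**Figure D3:**
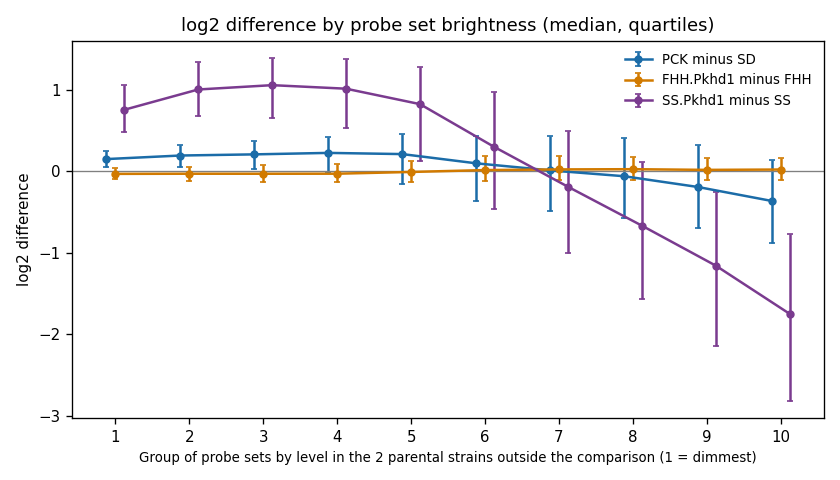
Median log2 difference (points; bars are quartiles) of each cystic strain from its parent in 10 equal groups of probe sets, ranked on their level in the 2 parental strains outside the comparison. For SS.Pkhd1 the median ran from 0.75 in the dimmest group to -1.75 in the brightest, for PCK from 0.15 to -0.37 and for FHH.Pkhd1 from -0.03 to 0.02.

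In SS.Pkhd1 more members fell than rose in each of the following lists. Oxidative phosphorylation had 22 of 24 lower and 0 higher (Uqcrfs1 -5.88 ± 0.12, Sdhb -5.19 ± 0.10), fatty acid oxidation 17 of 21 lower and 2 higher (Hadhb -4.69 ± 0.10), and proximal tubule 22 of 28 lower and 2 higher (Fbp1 -5.89 ± 0.12, Aqp1 -5.73 ± 0.15). The loop of Henle and distal tubule list had 9 of 15 lower and 3 higher (uromodulin, Umod, -4.67 ± 0.08), glutathione and oxidative stress 21 of 23 lower and 2 higher (Gclc -4.63 ± 0.08), xenobiotic and steroid metabolism 12 of 20 lower and 3 higher (Hao2 -5.61 ± 0.08) and cholesterol synthesis 12 of 18 lower and 1 higher (Idi1 -3.49 ± 0.10). Extracellular matrix and fibroblast had 20 of 31 lower and 4 higher (Fn1 -4.89 ± 0.11, Dcn -4.33 ± 0.09), tubule injury 15 of 23 lower and 5 higher (Cd24 -4.45 ± 0.10), cell division 16 of 28 lower and 3 higher (Mcm6 -3.35 ± 0.13), and cystic disease and cilium 11 of 24 lower and 2 higher (Bbs2 -4.88 ± 0.10). Beta-actin from the middle of the transcript fell by 4.92 on the same arrays, and signal from its 3' end fell by 2.02.

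In SS.Pkhd1 more members rose than fell in other lists. The lymphocyte list had 15 of 17 higher and 0 lower (Prf1 2.40 ± 0.15, Cd3e 2.25 ± 0.13, Cd4 1.62 ± 0.16), from SS levels of 3.93, 3.86 and 3.67. The list median was 1.23, where matched random lists had 0.92 (percentile 96.9). After cyclic loess normalization 7 members of the lymphocyte list were called. Immediate early genes had 9 of 15 higher and 1 lower (Fosl1 1.55 ± 0.16, Egr1 1.32 ± 0.11), with a median of 0.78 where matched random lists had -0.17 (percentile 99.5). Their members included bright genes such as Egr1, at 7.61 in SS. The list of cyclic AMP and chloride secretion had 8 of 21 higher and 5 lower (Gnas -5.73 ± 0.18), and EGF receptor 6 of 11 higher and 3 lower (Ereg 2.08 ± 0.13, Egf -2.63 ± 0.08). The medians of these lists were not extreme among matched random lists, at percentiles 79.5 and 75.8. Of all probe sets called higher, 10654 lay below the median signal of the array and 3070 above it, and of those called lower, 849 and 7639. Hybridisation controls were 1.87 log2 higher on the SS.Pkhd1 arrays than on those of SS.

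In the remaining lists of SS.Pkhd1, principal cells had 6 of 12 lower (Hsd11b2 -2.03, and Aqp4 -4.70 with another probe set called higher), endothelium 9 of 14 lower (Plvap -1.48) and osmotic response 6 of 8 lower and 1 higher (Slc14a2 -2.56, with 2 of its 5 probe sets called higher). Their medians were not extreme among matched random lists, at percentiles 73.5, 30.0 and 32.8 in this order. Intercalated cells had 6 of 11 lower and 2 higher (Slc4a1 -3.27, Insrr 1.74), podocytes 5 of 11 lower and 2 higher (Nphs1 -1.51, Tgfbr3 1.43), smooth muscle 4 of 11 lower and 1 higher (Myh11 -1.76, Synpo2 0.91) and antigen presentation 6 of 14 lower and 2 higher (B2m -4.69). Macrophage and myeloid genes had 8 of 21 lower and 7 higher (Ptprc -2.14, Gpnmb 1.72), inflammatory signal 6 of 20 lower and 5 higher (Ptgs2 -2.72, Cxcl2 1.74), interferon response 7 of 19 lower and 4 higher (Ifit2 -3.03), and complement and acute phase 5 of 13 lower and 4 higher (Fga -2.32). Wnt had 5 of 18 each way (Lef1 2.39, Myc -1.83), renin-angiotensin and vasoactive 8 of 16 lower and 5 higher (Agtr1a -4.16, Agt 2.29), urothelium 4 of 9 lower and 3 higher (Upk1b -1.95, Krt5 1.69), adipose tissue 7 of 10 lower and 3 higher (Fabp4 -5.28), adrenal gland 2 of 9 lower and 3 higher (Hsd3b1 -3.72, Dbh 1.68), and red blood cells 2 of 7 each way (Hbb -3.24, Slc25a37 1.27). This last balance did not survive normalization, as the other 2 called members moved: Hba-a3 went from -0.85 to 0.37 after quantile normalization and 0.80 after cyclic loess, and Epb42 from 0.60 to -0.13 (adjusted p = 0.359) and -0.31. Medians and means differed in sign for the cyclic AMP and adrenal lists. The counts of every list in SS.Pkhd1 were the same adjusted over the list alone, and the spread of signal over probe sets was 1.57 on these arrays and 2.15 on those of SS.

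**Figure D4:**
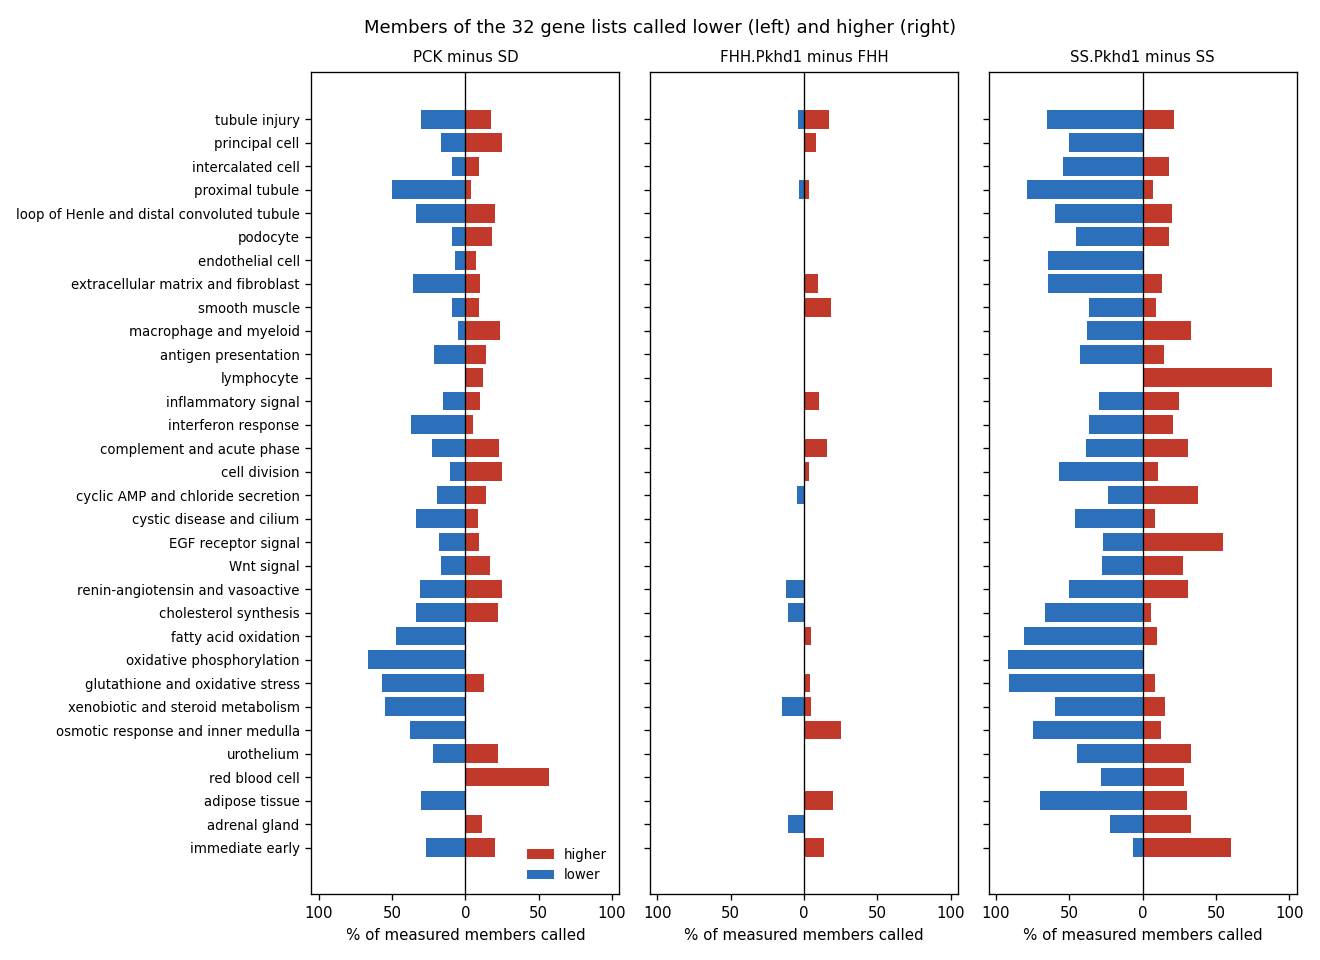
Percent of the measured members of each of the 32 gene lists called higher (red, right) and lower (blue, left) in each cystic strain against its parent. In oxidative phosphorylation, 0 of 24 were called in FHH.Pkhd1, 16 were lower in PCK and 22 were lower in SS.Pkhd1.

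In SS.Pkhd1, 22212 of 31042 probe sets were called by limma (13724 higher, 8488 lower), 71.6% of those tested. With 1 probe set per gene, 4737 of 10068 genes called were higher and 5331 lower. The median of all probe sets was 0.42, and 0.19 after quantile normalization, 0.18 after median centring and 0.02 after cyclic loess. The share of calls that were higher was 61.8% with the deposited values, 51.7% with median centring and 48.4% with cyclic loess. Among the genes chosen by the naming rule, the calls under cyclic loess of Plvap (-0.17), Synpo2 (0.47), Hsd11b2 (-0.44), Tgfbr3 (0.57), Aqp3, Foxi1, Eng, Myl9, Ifit1, Serping1, Fzd1, Pnmt, Dusp1, Havcr1 and Lypd2 ended with unchanged direction, and Fxyd4, Nfat5, Krt7, Hba-a3 and Epb42 changed sign. Under quantile normalization the calls of Myl9, Nfat5, Krt7, Pnmt, Lypd2, Fxyd4, Hba-a3 and Epb42 ended, where Hba-a3 changed sign and Fxyd4 and Epb42 lay at 0 within error. Cyclic loess also left 5 calls in the endothelial, 15 in the glutathione, 8 in the renin-angiotensin, 6 in the adipose, 4 in the osmotic and 3 in the urothelium list.

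A set of 70 probe sets was called in the same direction in the 3 backgrounds, 8 higher and 62 lower, where 17.4 and 9.30 would be expected if calls were independent. Calls were not independent, as PCK and SS.Pkhd1 shared 4104 lower calls where 1306 would be expected. The excess over 9.30 holds this overlap, so it does not measure how far all 3 backgrounds agree. The 70 probe sets represent 37 genes, 3 higher and 34 lower. The genes higher in all 3 were Havcr1 (1.33 ± 0.16 in PCK, 1.5 ± 0.16 in FHH.Pkhd1 and 0.86 ± 0.16 in SS.Pkhd1), Lypd2 (2.0 ± 0.15, 1.14 ± 0.15 and 0.82 ± 0.15) and the circadian transcription factor Tef (1.0 ± 0.10, 0.87 ± 0.10 and 1.13 ± 0.10). The SS.Pkhd1 calls of Lypd2 ended under quantile normalization (0.38), median centring (0.57) and cyclic loess (0.53), and that of Havcr1 under cyclic loess (0.44). Among genes lower in all 3, the log2 differences in the order PCK, FHH.Pkhd1 and SS.Pkhd1 were -2.71, -4.44 and -2.82 for Slco1a1, -3.54, -2.67 and -2.59 for Ugt2b35 and -1.80, -4.07 and -2.39 for Akr1c13 (SE between 0.11 and 0.18). Pzp, Akr1c1, the calcium-binding protein Rgn, the cation channel Trpv1, Mybl1, Resp18 and Dmrtc1c1 completed the 10 named, the smallest of their SS.Pkhd1 differences being that of Dmrtc1c1 (-1.15 ± 0.20). Without the SS.Pkhd1 arrays, PCK and FHH.Pkhd1 shared 23 probe sets higher and 85 lower, where 44.7 and 35.3 would be expected, and 296 went opposite ways, where 87.5 would be expected. The poly-A controls were 1.40 and 2.52 log2 higher in PCK and SS.Pkhd1 and fell by 0.36 in FHH.Pkhd1.

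**Figure D5:**
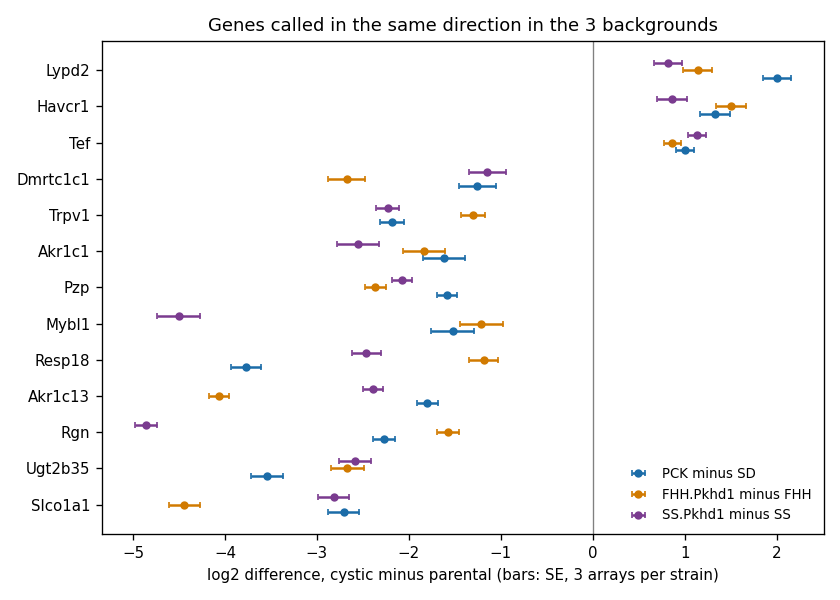
log2 difference of each cystic strain from its parent for genes called in the same direction in the 3 backgrounds; bars are SE, with 3 arrays per strain. Slco1a1 lay at -2.71, -4.44 and -2.82 in PCK, FHH.Pkhd1 and SS.Pkhd1, and Havcr1 at 1.33, 1.5 and 0.86.

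Over all probe sets the differences of PCK and SS.Pkhd1 correlated with a Pearson r of 0.690 and a Spearman rho of 0.619. For PCK and FHH.Pkhd1 these were -0.276 and -0.328, and for FHH.Pkhd1 and SS.Pkhd1 -0.248 and -0.295. These correlations are across probe sets, which are not independent replicates, and the comparisons share no arrays. PCK and SS.Pkhd1 also shared higher poly-A controls (1.40 and 2.52) and 5S ribosomal RNA (1.28 and 4.05). From the dimmest to the brightest group of probe sets their median differences ran from 0.15 to -0.37 and from 0.75 to -1.75, against -0.03 to 0.02 in FHH.Pkhd1. The correlations were not adjusted for this shared trend with brightness, and a shared trend adds to such a correlation. Of probe sets called in both, PCK and SS.Pkhd1 had 2133 higher, 4104 lower and 229 opposite, where 1521, 1306 and 3052 would be expected.

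Across backgrounds, with the 6 pools as the units, 1 probe set passed the limma test, and the annotation used gave no gene for it. It fell by 4.09 ± 0.36 (adjusted p = 0.00744), with -4.17 in PCK, -4.23 in FHH.Pkhd1 and -3.86 in SS.Pkhd1. At an unadjusted p under 0.05 there were 2453 probe sets, 277 higher and 2176 lower. Slco1a1 (-3.32 ± 0.43) and Ugt2b35 (-2.93 ± 0.38) came next among named genes, each with an adjusted p of 0.084, ahead of Akr1c13 (-2.75), Pzp (-2.01) and Akr1c1 (-2.0). The rises with the smallest p were Lypd2 (1.32 ± 0.39), Havcr1 (1.23 ± 0.37), Mt1 (1.83), Sox11 (1.67) and Nexmif (1.39), each with an adjusted p of 0.622, and Sox11 and Nexmif were not higher in FHH.Pkhd1 (-0.18 and -0.10). Without the FHH background, 2885 probe sets were called, and without the SD background 12. No probe set was called after quantile normalization, which is 0 by limma.

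Camera across backgrounds, with a preset correlation of 0.01, called 8 of the 32 lists. Oxidative phosphorylation (median -1.31, adjusted p = 7.43e-08), glutathione and oxidative stress (-0.87, adjusted p = 2.74e-05), proximal tubule (-0.92, adjusted p = 2.74e-05) and fatty acid oxidation (-1.0, adjusted p = 0.000505) were lower. So were xenobiotic and steroid metabolism (-0.80, adjusted p = 0.0013), cholesterol synthesis (-0.46, adjusted p = 0.0256) and extracellular matrix and fibroblast (-0.56, adjusted p = 0.0318). The lymphocyte list was higher (0.45, adjusted p = 0.00179). In FHH.Pkhd1 alone the list medians were 0.04 for oxidative phosphorylation, 0.0044 for proximal tubule, 0.17 for fatty acid oxidation, 0.06 for xenobiotic and steroid metabolism, 0.18 for extracellular matrix and fibroblast and -0.13 for lymphocyte, each opposite in sign to the test. By the median, only glutathione and oxidative stress (-0.08) and cholesterol synthesis (-0.21) had the sign of the test in FHH.Pkhd1. By the mean, xenobiotic and steroid metabolism (-0.36) and proximal tubule (-0.05) had it too. The proximal tubule median of 0.0044 had a standard error of 0.121 even with its genes taken as independent, so its sign is not settled. None of these 8 calls held with an estimated correlation, where each had adjusted p = 0.860 with an estimated correlation. Without the SS background 5 lists were called, and the matrix list changed direction (adjusted p = 0.907), while lymphocyte (adjusted p = 0.526), fatty acid oxidation and cholesterol synthesis (each adjusted p = 0.0691) were not called. The cholesterol synthesis list by camera across backgrounds was not called without the FHH background either (adjusted p = 0.0843). The PCK and SS.Pkhd1 pools behind these medians had 5S ribosomal RNA 1.28 and 4.05 log2 above their parents. The median, mean and test of the 8 lists had 1 sign each. The median differed in sign from the mean or the test for the smooth muscle, macrophage, complement, cyclic AMP, renin-angiotensin, urothelium and adrenal lists.

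The cystic minus parental differences, called effects here with no cause assigned, were also compared between backgrounds by testing the difference itself. Highest and lowest refer here to genes, each by its chosen probe set, and not to all probe sets. The PCK effect minus the FHH.Pkhd1 effect was highest for RT1-Bb (4.19 ± 0.18), AKR1C3l1 (3.65 ± 0.17) and Cyp4a8 (3.31 ± 0.13), and lowest for Ephx2 (-3.89 ± 0.30), Ccl2 (-3.79 ± 0.14) and Dcn (-3.70 ± 0.13). The PCK effect minus the SS.Pkhd1 effect was highest for Alb (7.50 ± 0.16), Fam111a (6.18 ± 0.19) and Aldh6a1 (5.05 ± 0.13), and lowest for Spetex2l1 (-5.45 ± 0.19), Pcdh9 (-5.03 ± 0.22) and RT1-T24-3 (-4.32 ± 0.17). The FHH.Pkhd1 effect minus the SS.Pkhd1 effect was highest for Aldh6a1 (7.81 ± 0.13), Igfbp7 (7.19 ± 0.14) and Nnt (6.74 ± 0.27), and lowest for Spetex2l1 (-6.06 ± 0.19), Dhrs7l1 (-4.51 ± 0.18) and Rd3 (-3.81 ± 0.20). Limma called 9930 probe sets in the first of these contrasts (4523 higher, 5407 lower), 18930 in the second (7920 higher, 11010 lower) and 22569 in the third (8656 higher, 13913 lower). With 1 probe set per gene the balance turned, with 5310 genes higher and 3419 lower in the second and 5325 higher and 4911 lower in the third. The largest adjusted p of the genes named here was 1.24e-08, that of Ephx2. The second count was 11758 after cyclic loess, where 53.3% were higher in place of 41.8% (56.5% with median centring), and the third had 51.0% higher in place of 38.4%. Poly-A controls differed by 1.40 between PCK and SD and by 2.52 between SS.Pkhd1 and SS.

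The parental strains were compared to show how far the backgrounds themselves differ. Their poly-A controls stood at 9.27 in SD, 9.96 in FHH and 9.44 in SS. RT1-Bb was 4.24 ± 0.13 higher in FHH and 4.42 ± 0.13 higher in SS than in SD, with a second probe set called the opposite way in each. RT1-T24-3 was lower in both (-3.62 ± 0.12 and -3.45 ± 0.12). FHH had higher Fam111a (3.62 ± 0.13) and the lens crystallin Cryga (2.09 ± 0.11) than SD, and lower Nat8b (-4.36 ± 0.10) and Ugt2b35 (-3.99 ± 0.18). SS had higher steroid dehydrogenase Hsd3b1 (3.52 ± 0.19) and Alb (2.98 ± 0.11) than SD, and lower Pcdh9 (-3.85 ± 0.16) and Ephx2 (-3.32 ± 0.21). FHH exceeded SS in Pcdh9 (5.62 ± 0.16), Ephx2 (3.14 ± 0.21) and Fam111a (3.04 ± 0.13), and lay below it in Nat8b (-4.61 ± 0.10), Hsd3b1 (-4.04 ± 0.19) and the urea cycle enzyme Cps1 (-3.98 ± 0.13). Adipose tissue genes had 6 of 10 members higher in FHH than in SD and proximal tubule genes 6 of 28 lower and 1 higher, and adrenal genes had 4 of 9 higher in SS than in SD. Limma called 1130 probe sets between FHH and SD (398 higher, 732 lower), 791 between SS and SD (351 higher, 440 lower) and 1488 between FHH and SS (526 higher, 962 lower), and the largest adjusted p of the genes named here was 8.81e-09. Between SS and SD the excess of lower calls turned after cyclic loess normalization, with 438 higher and 378 lower.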

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

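The tests of array scale, of a shared response, of the androgen and the clock patterns were chosen only after the results were seen; that of compressed signal and the splits of the arrays were written before.

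In SS.Pkhd1 against SS, most probe sets were called, dim ones mainly higher and bright ones mainly lower, on arrays whose hybridisation controls, poly-A controls and 5S ribosomal RNA were 1.87, 2.52 and 4.05 log2 higher. Array scale or distribution is argued against as the whole cause by 18614 calls after quantile normalization and 15638 after cyclic loess. Cyclic loess lowered the standard deviation of the differences from 1.41 to 1.11. The differences correlated with those of FHH.Pkhd1 at r = -0.248 across probe sets. This cannot decide on a shared response, as the trend with brightness in SS.Pkhd1 enters the correlation. Of probe sets called in both, 31 were higher, 116 lower and 303 opposite, where 157, 60.4 and 195 would be expected. Compressed signal from little or degraded target RNA may account for much of the pattern: of 2452 genes with probe sets at least 2 log2 apart, 27.6% had the brightest called lower and the dimmest called higher, against 0.326% the other way and 1.35% in PCK. Whether degradation took part stays open, as 3' minus 5' signal was higher than in SS for beta-actin (3.66 and 2.98) and lower for Gapdh (-0.08 and 0.94). A biological difference between the SS.Pkhd1 and SS pools stays open and untested, since no other pool of these strains was used here.

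In FHH.Pkhd1, some genes known to depend on androgen in the rodent kidney were lower than in FHH. A pool of female animals is argued against by the Y-linked genes, of which the lower, Eif2s3y, lay at -0.22 ± 0.23, and by Xist at 1.88 in FHH.Pkhd1 and 1.91 in FHH, though a small share of female RNA was not excluded. Fewer proximal tubule cells in the FHH.Pkhd1 pool are argued against by the median of the proximal tubule list, 0.0044. Its standard error of 0.121 comes from the spread of 28 genes taken as independent, so it does not cover differences between pools. Lower androgen exposure of the pooled males is a candidate explanation: of 7 androgen-dependent genes outside the 10 largest falls, 4 were lower (Kap -0.60 ± 0.08, Odc1 -1.32 ± 0.08, Slc22a2 -2.07 ± 0.10 and Agt -1.47 ± 0.10) and 3 were not called (Hsd11b1 -0.58 ± 0.18, adjusted p = 0.0709, Slc22a6 -0.06 ± 0.08 and Gusb 0.18 ± 0.10), with a median of -0.60. This list was written after several of its values had been seen, and Slc22a2 and Agt had already been reported as falls in fixed lists, so it remains a hypothesis, and the maturity of the animals was not measured.

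Clock genes differed between FHH.Pkhd1 and FHH: of 11 genes in the phase of Dbp 7 were higher (median 0.87), and of 5 in the opposite phase 2 were lower, Bmal1 (-1.61 ± 0.17) and Npas2 (-1.35 ± 0.10). The medians of these groups differed by 1.39. Another time of day at collection cannot be told apart from an effect of the strain, as each strain is 1 pool. The same measure was -1.70 between FHH and SD, -2.13 between SS and SD, -0.49 in PCK and 0.83 in SS.Pkhd1. In the last 2 the Dbp group was mixed, with 2 higher and 4 lower in PCK and 4 higher and 4 lower in SS.Pkhd1. Dbp itself lay at -2.01 in SS.Pkhd1, so the value of 0.83 does not show the shift seen in FHH.Pkhd1. A stronger glucocorticoid signal may also contribute, as 2 of 3 glucocorticoid-induced genes measured were higher (Tsc22d3 0.81 ± 0.09, Sgk1 0.73 ± 0.08) and Fkbp5 lay at 0.13 ± 0.12, with a median of 0.73. Between FHH and SD, Tsc22d3 (-0.91) and Sgk1 (-0.97) moved with the clock measure (-1.70), though in PCK and SS.Pkhd1 they did not both do so. These 3 genes therefore do not separate such a signal from another time of day.

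The remaining results are given as values. The effects in PCK and FHH.Pkhd1 differed, by a test of the difference, in 9930 probe sets. Among genes, each by its chosen probe set, RT1-Bb (4.19), AKR1C3l1 (3.65), Cyp4a8 (3.31), Ephx2 (-3.89), Ccl2 (-3.79) and Dcn (-3.70) were at the ends. Over all probe sets the difference ran from -6.44 to 6.36. The effects in PCK and SS.Pkhd1 differed in 18930. Alb (7.50), Fam111a (6.18), Aldh6a1 (5.05), Spetex2l1 (-5.45), Pcdh9 (-5.03) and RT1-T24-3 (-4.32) were at the ends among genes, and the lowest of all probe sets lay at -6.58. The effects in FHH.Pkhd1 and SS.Pkhd1 differed in 22569. Aldh6a1 (7.81), Igfbp7 (7.19), Nnt (6.74), Spetex2l1 (-6.06), Dhrs7l1 (-4.51) and Rd3 (-3.81) were at the ends among genes, and the lowest of all probe sets lay at -9.23. Control probe sets outside the tested ones also differed in PCK against SD, where hybridisation controls were 0.95, poly-A controls 1.40 and 5S ribosomal RNA 1.28 log2 higher. In PCK, 3' minus 5' signal was higher than in SD for beta-actin (4.30 and 3.34) and for Gapdh (2.37 and 1.38). A contribution of little or degraded target RNA to the PCK calls therefore stays open.

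Other splits of the arrays were fitted for each count. With 6 arrays there are 10 splits, too few for a share under 0.05. The highest count of the others was 0, against 8216 for PCK, 576 for FHH.Pkhd1, 22212 for SS.Pkhd1, 1130 for FHH and SD, 791 for SS and SD and 1488 for FHH and SS. For the differences of effects, 100 splits within the backgrounds were fitted. The real split gave the highest count for PCK against FHH.Pkhd1 (1 of 100, 9930, highest other 9236) and for FHH.Pkhd1 against SS.Pkhd1 (1 of 100, 22569, highest other 22467). Those highest others kept PCK apart from SD, or SS.Pkhd1 apart from SS, and mixed FHH.Pkhd1 with FHH. For PCK against SS.Pkhd1, 10 of 100 splits reached the real count of 18930, the highest other being 22596, so chance was not excluded by this count. Its 9 other splits all kept SS.Pkhd1 and SS apart and mixed PCK with SD, which points to a structure of the samples, and the highest count of a split that kept neither apart was 0. For calls alike in 3 backgrounds the real split (70) was the 1 of 100 drawn with as many, the highest other being 0. A split that mixes repeat arrays of different pools puts the difference between pools into the array spread, so none of the splits of arrays above bears on chance differences between pools or animals. Across backgrounds there are 4 splits of the 6 pools, too few for a share under 0.05. There the real count was 1 and the highest other 0 (1 of 4 with as many), and for gene lists the real count was 8 and the highest other 11 (3 of 4 with as many).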

How the results depend on the processing

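Cyclic loess normalization and the fits without arrays were chosen only after the data were seen; the other alternatives were planned. Of 391 named values, direction and call were the same in 391 with a trended robust prior, with only the arrays compared, with no fold floor and with 1 probe set per gene, in 390 with array weights, 389 with median centring, 362 with quantile normalization, 364 with cyclic loess, 370 with treat and 328 with a 2-fold floor. Without the SS.Pkhd1 arrays 221 of 221 and without the PCK and SS.Pkhd1 arrays 76 of 76 were the same. Leaving out arrays of other strains does not alter a difference, and neither do the prior, the floors, treat or 1 probe set per gene. Direction could therefore not change under these settings, and only the call could. The named values were chosen as called, and dropping the floor cannot end a call. In SS.Pkhd1 under quantile normalization the difference vanished for Fxyd4 (2e-04 in place of -1.18, adjusted p = 0.999) and Epb42 (-0.13 in place of 0.60, adjusted p = 0.359). The direction reversed for Hba-a3 (0.37 in place of -0.85), and under cyclic loess for Fxyd4 (0.39), Nfat5 (0.30 in place of -1.29), Krt7 (0.40 in place of -1.15), Hba-a3 (0.80) and Epb42 (-0.31); the cause was not tested. The extracellular matrix and fibroblast list by camera across backgrounds reversed without the SS background (adjusted p = 0.907) and kept its direction without FHH (0.000291) or SD.

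With a 2-fold floor the counts were 3286 for PCK, 112 for FHH.Pkhd1 (40 higher and 72 lower, in place of 355 and 221), 4442 and 10403 for the PCK effect against those of FHH.Pkhd1 and SS.Pkhd1, 327 for FHH and SD, 208 for SS and SD, 371 for FHH and SS, and 21 alike in 3 backgrounds, fewer by construction. With no floor they were 15812 for PCK, 1417 for FHH.Pkhd1, 2722, 1857 and 3902 for the parental contrasts in that order, and 214 alike. Treat gave 229 for FHH.Pkhd1, 716, 420 and 938 for the parental contrasts, and 40 alike. One probe set per gene, which tests fewer features, gave 4474 for PCK, 297 for FHH.Pkhd1, 10068 for SS.Pkhd1, 5334, 8723 and 10231 for the differences of effects, 584, 380 and 709 for the parental contrasts, and 37 alike. Probe sets above the median alone gave 10709 for SS.Pkhd1 and 9399 and 10878 for its differences from PCK and FHH.Pkhd1, by construction. Cyclic loess gave 11758 for PCK against SS.Pkhd1. PCK and FHH.Pkhd1 alone had 108 alike.

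Across backgrounds the 1 call became 0 without the background term, 0 with bright probe sets only, 0 after quantile normalization, 10 with a trended robust prior, 28 with the pool as a random block, and 15 with the replicate block in addition. For comparison, 2453 probe sets had an unadjusted p under 0.05 by limma. It became 12 without the SD background and 2885 without the FHH background, a range of 1 to 2885. The 8 gene lists became 0 with an estimated correlation and 5 among bright genes, and leaving out a background gave from 5 without SS to 11 without SD; the cause was not tested. Leaving out arrays gave 8073 to 8409 for PCK, 459 to 559 for FHH.Pkhd1, 21932 to 22359 for SS.Pkhd1, 9502 to 10054, 18412 to 19356 and 22355 to 22724 for the differences of effects, 1019 to 1103, 678 to 746 and 1406 to 1460 for the parental contrasts, and 61 to 74 alike. The array numbers did not pair the arrays: residual correlations of arrays with the same number ran from -0.0683 to 0.206, and not every array correlated best with its own number. A block on array number, which does not alter the differences when every strain has each number, left the 391 named values the same. Signal near background limits dim probe sets, and arrays repeat 1 pool.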

Other observations

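The tests of genes next to Pkhd1 and the levels given here were chosen only after results were seen. Hsd3b1, Cyp11a1 and Akr1b7, genes expressed in steroid-producing tissue, stood above the other pools in SS. Hsd3b1 had a log2 signal of 8.53 ± 0.07 (SD, n = 3 arrays) in SS, 5.01 ± 0.27 in SD, 4.49 ± 0.09 in FHH and 4.80 ± 0.56 in SS.Pkhd1. Cyp11a1, the enzyme that opens steroid synthesis from cholesterol, stood at 7.13 ± 0.20 in SS, 4.15 ± 0.14 in SD and 4.77 ± 0.07 in SS.Pkhd1. Cyp11b1, which is specific to the adrenal cortex, was at 2.08 ± 0.05 in SS, 1.98 ± 0.08 in SD and 2.67 ± 0.63 in SS.Pkhd1. Star stood at 4.67 ± 0.14, 3.55 ± 0.13 and 4.53 ± 0.16 in the same order, Cyp21a1 at 4.87 ± 0.24, 3.97 ± 0.16 and 5.28 ± 0.16, and Akr1b7 at 3.98 ± 0.49, 1.99 ± 0.14 and 3.07 ± 0.24. Brown fat genes differed between the pools as well. The uncoupling protein Ucp1 stood at 7.83 in SD, 6.70 in PCK, 9.03 in FHH, 10.03 in FHH.Pkhd1, 8.71 in SS and 5.17 in SS.Pkhd1, and Cidea at 6.94, 6.41, 8.07, 8.72, 7.47 and 5.56 in the same order.

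At the antigen genes RT1-Bb and RT1-T24-3, which were among the largest differences of PCK from SD, the SD pool also stood apart from the FHH and SS pools. RT1-Bb had a signal of 4.53 in SD, 9.06 in PCK, 8.77 in FHH and 8.95 in SS. RT1-T24-3 stood at 7.78 in SD, 4.29 in PCK, 4.16 in FHH and 4.34 in SS. At Fam111a and Ephx2 the parental pools differed in other ways. Fam111a was at 4.72 in SD, 8.51 in PCK, 8.34 in FHH and 5.30 in SS, and Ephx2 at 9.04, 5.32, 8.86 and 5.72.

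The sex-linked genes also differed between pools that the labels give as male. The Y-linked genes Uty and Eif2s3y fell by 3.28 ± 0.17 and 2.50 ± 0.23 in SS.Pkhd1 against SS, and lay at -1.18 ± 0.17 and -0.41 ± 0.23 in PCK against SD, where only Uty was called. Xist had a signal of 3.13 ± 0.18 in SS.Pkhd1 and 1.92 ± 0.11 in SS, and of 2.30 ± 0.35 in PCK and 2.01 ± 0.02 in SD (SD, n = 3 arrays). The poly-A controls were 2.52 and 1.40 log2 higher on the SS.Pkhd1 and PCK arrays than on those of their parents.

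A hypothesis was tested that donor DNA around Pkhd1 in FHH.Pkhd1 could bring differences in neighbouring genes. Of 76 measured genes among the 60 nearest on each side, 3 were called (3.95%), against 290 of 14141 others (2.05%; Fisher's exact test, two-sided, p = 0.207, adjusted p = 0.620 over the 3 cystic strains). The 3 were Adgrf1 (-0.88 ± 0.13), Gsta3l1 (0.92 ± 0.17) and Tmem14a (-1.15 ± 0.13), and so few calls leave the hypothesis undecided. In PCK 27 of 76 (35.5%) and in SS.Pkhd1 55 of 76 (72.4%) were called, against 31.5% and 70.8% of the others.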
